A study of Homo sapiens with 6 samples.

How the data were processed

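RNA-seq of HaCaT cells was analysed from the processed tables of 6 libraries, 3 control and 3 UVB. Per the labels' protocols, cells were grown in 60 mm dishes, cultured for 24 h after irradiation and lysed in Trizol, and libraries were made from 1 µg of total RNA. Groups were taken from the sample titles. HISAT2 2.0.5, StringTie and DESeq and the human build hg38 (GRCh38) are named per the submitters' processing notes. The counting program, its strand setting, the annotation release and the source of the repeat annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and values of genes with shared exons are uncertain.

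The authors deposited a table of FPKM values for 58735 genes and 771683 repeat copies under 595 repeat names. All 58735 gene identifiers are those of GENCODE release 29, and 58643 gene lengths equal the merged exons of that release, so gene coordinates and biotypes were taken from it. The authors also deposited read counts of 74 repeat copies in 2 sheets with equal counts. With those counts the number of reads assigned per library followed from the FPKM values. Of non-zero FPKM values, 100% then gave whole numbers within a tolerance of 0.01. Whole numbers do not show that each unit is a single read. Some low gene values were all multiples of 4, such as EDNRB with 12, 8 and 4 in controls and 0, 4 and 0 after UVB. Others were not, such as IL12A with 49, 19 and 67 in controls. Read numbers, and tests on recovered reads, take each unit as a read, which is not known. The assigned reads were 69373448, 66272443 and 81303733 in the controls and 72517243, 88484020 and 79331735 after UVB. FPKM had thus been scaled by reads on genes and repeats together. The deposited tables also hold the authors' log2 fold changes and their standard errors, test scores and p-values from a comparison of the 2 groups, per the file headers. Their mean normalised counts in all 830418 rows equal recovered counts divided by median-ratio size factors over genes and repeats together, within a relative tolerance of 1e-06. The sheet is a selection of higher copies. A further 99 copies met the same criteria and are not in it, 11 of them with a mean at least as high as the lowest in the sheet.

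Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (eBayes with a mean trend) in R 4.3.3. Fold changes are on this scale. Calls used a Benjamini-Hochberg adjusted p under 0.05. Gene lists (27) were fixed before the data were examined, and the 23 with at least 5 tested members were tested with camera at its preset correlation of 0.01. Of these, 12 passed, and 6 passed with an estimated correlation: interferon-stimulated genes, RNA sensing, cytokines, early response, G2 and mitosis, and histones. The count sheet was tested with edgeR 4.0.16 (quasi-likelihood, TMM within the sheet, filterByExpr), and DESeq2 1.42.0 was an alternative. Repeat copies of the whole table were tested with limma like genes, and sums by repeat name on log2(RPM + 0.1). Both of these were added after the data were seen. An edgeR test on recovered reads, with TMM scaling, was run as an alternative for genes, repeat copies and names, because FPKM are not counts. Other alternatives were pseudocounts, filters, scalings, a replicate block and leaving out each library. Tests of single values are exact permutation tests in scipy 1.17.1.

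The genes named were chosen by rules fixed before the data were examined. They are the 14 genes of the RIG-I pathway, the 10 highest and 10 lowest log2 fold changes among protein-coding genes with adjusted p under 0.05, a mean of at least 1 FPKM and no overlap of replicates, and up to 4 members per list with the largest change, or up to 2 by level where none passed. In the sheet, the 5 copies with the highest mean count were named because fewer than 3 passed. Other genes, repeat copies and repeat names in the text were chosen after their values were seen.

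Each test was checked on data simulated from the real means and library sizes, in 5 draws with 200 changed features (40 for repeat names), under a trended and a single dispersion. For genes, limma recovered 97.6% of 4-fold and 64.3% of 2-fold increases with the trended dispersion, and 6.2% of its calls were unchanged genes. With a single dispersion these were 100%, 72.4% and 8.7%, so false calls in the simulation somewhat exceeded the nominal 5%. The share of false calls depends on how many genes change. In the real data 4167 genes were called, far more than the 200 changed here, so these shares need not carry over. For repeat copies limma recovered 13.2% of 4-fold and 1.2% of 2-fold increases, and 26% of its 50 calls were unchanged copies, against 44.8%, 2.9% and 11.1% for edgeR (trended dispersion). That simulated edgeR test used no TMM scaling, unlike the real one. With a single dispersion limma recovered 12.8% of 4-fold increases, and 27.5% of its calls were unchanged copies. Unchanged copies reached an unadjusted p under 0.05 in 5.12% of cases with the trended dispersion (limma). For repeat names limma recovered 92% of 2-fold increases with the trended dispersion, and 2.2% of its calls were unchanged names, against 100% and 6% with a single dispersion. When all 74 sheet copies were raised 2-fold, scaling within the sheet called 0% of them and whole-table library sizes called 23.2%. Camera called 5 of 5 lists raised 1.5-fold and 1 of 125 unchanged lists. Simulated genes were drawn independently and lists were random, so this cannot show how the preset correlation performs for lists of correlated genes.

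With each recovered unit taken as a read, replicates of a group differed by more than sampling noise, so none was counted as a duplicate. The same replicate numbers occur in both groups, but no label ties them to a day or batch. Coordinates of repeat copies, and the reads themselves, were not used here.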

Results

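RNA was sequenced from HaCaT cells, an immortalised line of human keratinocytes, the main cell type of the epidermis. One group of 3 dishes served as control and another group of 3 received ultraviolet B (UVB) light at a dose labelled 50 mJ, for which the labels give no area. The labels state that irradiated cells were cultured for 24 h before RNA was harvested. The study's title asks whether ultraviolet light induces human endogenous retroviruses (HERVs), the remains of ancient retroviral insertions, and whether these activate signalling through RIG-I, a cytoplasmic sensor of viral RNA. Nothing in the labels says that the 3 dishes of a group were prepared independently, so p-values measure only the spread between these samples, which may be technical. The control libraries held 69373448, 66272443 and 81303733 assigned reads, and the UVB libraries held 72517243, 88484020 and 79331735. These totals take each unit of the recovered counts as a read, which is not known. Reads on repeat copies made up 0.858% ± 0.0893 of assigned reads in the controls and 0.771% ± 0.0208 after UVB (SD, n = 3 each). This difference was within the spread between replicates (2-sided exact permutation p = 0.2, where 0.1 is the smallest value that 3 against 3 samples allow).

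The first comparison asked which genes differed between UVB-treated and control cells. Interferon-stimulated genes were higher after UVB (43 of 46 tested, none lower), as were most cytokine and NF-κB genes (19 of 26, 1 lower) and immediate early genes (17 of 27, 1 lower). Genes of G2 and mitosis were lower (28 of 35, none higher), as were most of the replication histones tested (9 of 13, 1 higher). These lists also passed their set tests, given with each list in turn. Of 14921 genes tested, 2530 were higher and 1637 were lower (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). At least 1 log2 unit separated the groups for 72 of the higher and 133 of the lower genes. Values near 0 change less on this scale than their ratio does. An edgeR count test on the recovered reads split its calls more evenly, into 2100 higher and 2050 lower genes. Both tests called 1945 genes higher and 1519 lower. The count test also used TMM scaling, whereas FPKM were not rescaled for limma. The effects of test and scaling on this balance cannot be told apart here. Leaving out UVB replicate 3 lowered the number of higher genes to 1639.

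The RIG-I pathway and the interferon response were examined through 14 genes chosen for the study's title. RIG-I itself, encoded by DDX58 (ENSG00000107201, chromosome 9, 32455705 to 32526324, GRCh38), rose from 11.5 ± 1.07 FPKM in controls to 29.99 ± 0.162 FPKM after UVB (SD, n = 3 each). Its log2 fold change was 1.32 ± 0.0684 (SE, limma adjusted p = 0.000139). The related RNA sensors IFIH1, which encodes MDA5, and DHX58, which encodes LGP2, rose by log2 fold changes of 0.79 and 1.21. ISG15, a ubiquitin-like protein induced by interferon, rose from 107 ± 1.65 to 390 ± 11.5 FPKM. IRF7, a transcription factor of the interferon response, rose from 28.0 ± 1.33 to 59.4 ± 1.69 FPKM. The antiviral genes MX1, OAS1 and IFIT1 rose with log2 fold changes of 1.46, 1.13 and 0.95. The chemokine gene CXCL10 passed the test at low level, at 0.207 ± 0.115 FPKM in controls and 0.820 ± 0.103 FPKM after UVB. In all, 9 of the 13 genes tested were higher and none was lower (limma). All 13 stayed on the same side of the threshold with the edgeR count test. As 43 of 46 interferon-stimulated genes were also higher, the rise of these 9 is not particular to the RIG-I pathway. RNA levels do not measure signalling through RIG-I.

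The other 4 genes tested did not pass. MAVS, the mitochondrial adaptor downstream of RIG-I, measured 19.1 ± 1.67 FPKM in controls and 19.0 ± 0.380 FPKM after UVB. The kinase gene TBK1 measured 10.8 ± 0.248 and 11.6 ± 1.27 FPKM, and the transcription factor gene IRF3 measured 16.5 ± 3.70 and 18.8 ± 1.06 FPKM. CCL5 measured 10.1 ± 2.99 and 10.4 ± 3.04 FPKM. IFNB1, which encodes interferon beta, lay under the expression filter, with 0, 0 and 13 reads in the control libraries and 0, 9 and 9 reads after UVB, too few to compare.

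**Figure D1:**
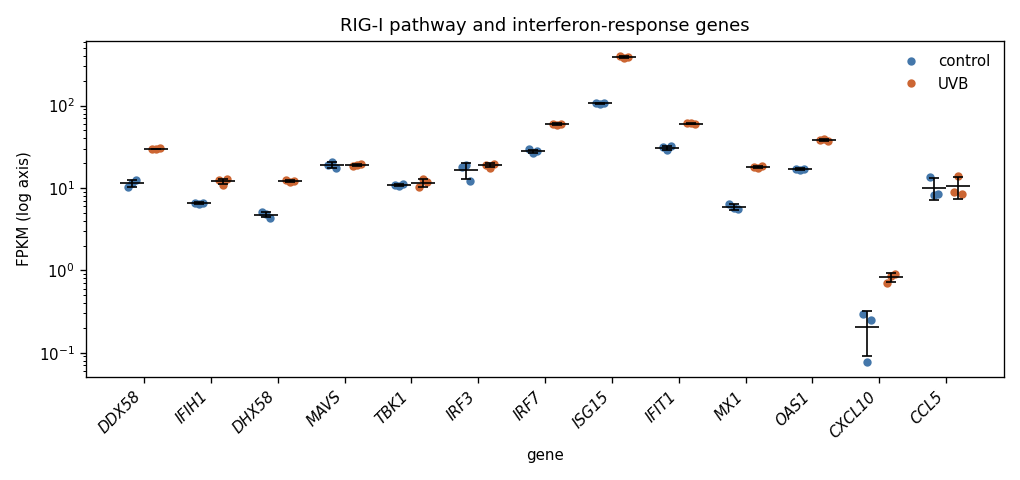
FPKM on a log axis for the 13 tested genes of the RIG-I pathway and interferon response. Points are the 3 libraries of each group, and black marks are the mean with the SD. Libraries of the 2 groups are separate for DDX58, at 11.5 ± 1.07 and 29.99 ± 0.162 FPKM, and overlap for CCL5.

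The wider interferon-stimulated list, fixed before the data were examined, was higher as a set. Of its 46 tested members, 43 were higher and none was lower over all genes tested, and 45 were higher when adjusted over the list alone. The median log2 fold change was 0.86 (limma camera adjusted p = 8.2e-25, and adjusted p = 0.024 with an estimated correlation). IFI6 rose from 160 ± 15.9 to 573 ± 24.1 FPKM, USP18 from 12 ± 0.663 to 42.0 ± 2.22 FPKM and MX2 from 2.29 ± 0.295 to 9.26 ± 1.82 FPKM. The 3 members that did not pass over all genes were SAMD9L, IFI44 and CCL5, with log2 fold changes of 1.16, 0.35 and 0.05. In the list of RNA-sensing pathway genes, 13 of 28 tested members were higher, 15 did not pass and none was lower, with the same 13 and 0 adjusted over the list alone. Its median was 0.25 (camera adjusted p = 9.1e-05, and adjusted p = 0.046 with an estimated correlation). TICAM1, the adaptor of the receptor TLR3, rose by a log2 fold change of 0.80, and ADAR, an RNA editing enzyme, by 0.72. The interferon-stimulated and RNA-sensing lists share members with the RIG-I pathway genes above, such as ISG15 and DDX58, so these results are not independent.

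Of the interferons and their receptors, 7 of 14 listed genes passed the expression filter, and 3 of these were higher. IFNL1, a type III interferon, was at 0.327 ± 0.158 FPKM in controls and 1.37 ± 0.445 FPKM after UVB. IFNGR1 and IFNLR1, both receptor genes, had log2 fold changes of 0.46 and 0.37. The call of IFNLR1 was lost without control replicate 2 or 3 or UVB replicate 1 or 3, at log2 fold changes of 0.3715, 0.3371, 0.3703 and 0.3103. The list as a whole did not pass (camera adjusted p = 0.12), with 3 higher and none lower adjusted over the list alone, and it passed without control replicate 3 (adjusted p = 0.0466). In the MHC class I list, 9 of 20 members were higher and 2 lower, and 9 and 3 adjusted over the list alone. TAP1, the peptide transporter, and HLA-E rose by 0.75 and 0.65. That list's call was near the threshold (camera adjusted p = 0.048) and was lost with an estimated correlation (adjusted p = 0.28). It was also lost without control replicate 2 or 3 or UVB replicate 1 (adjusted p = 0.0831, 0.0591 and 0.0645).

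Inflammatory and early response genes were also higher. Of 26 tested cytokine and NF-κB genes, 19 were higher and 1 was lower, over all genes and adjusted over the list alone, with a median of 0.61 (camera adjusted p = 1.1e-06, and adjusted p = 0.046 with an estimated correlation). Without the expression filter the cytokine median was 0.40. TNFAIP3, a feedback inhibitor of NF-κB, rose from 3.86 ± 0.273 to 13.4 ± 0.455 FPKM, CXCL8 from 4.09 ± 0.0887 to 12.7 ± 0.729 FPKM, and PTGS2, which encodes cyclooxygenase-2, from 2.58 ± 0.149 to 8.15 ± 0.513 FPKM. CCL2 was the member that fell, with a log2 fold change of -0.95. Of 27 AP-1 and immediate early genes, 17 were higher and 1 was lower, or 21 and 1 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 8.4e-08, and adjusted p = 0.046 with an estimated correlation). JUN rose from 4.21 ± 0.129 to 16.4 ± 0.918 FPKM, and EGR1 and the EGF-receptor ligand gene AREG rose by 1.19 and 1.21. FOS did not pass, at a log2 fold change of -0.04.

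Stress and DNA damage genes moved in both directions. In the list of unfolded protein and ATF4 genes, 12 of 25 were higher and 5 lower, or 14 and 5 adjusted over the list alone. DDIT3, whose exons overlap another gene over 39.6% of their length, rose by 1.504, and PPP1R15A and CHAC1 rose by 1.52 and 1.43. The chaperone genes HSPA5 and CALR fell by 0.23 and 0.32 on the log2 scale. The list's median was 0.33 (camera adjusted p = 0.0038), and its call was lost with an estimated correlation (adjusted p = 0.20). Of 34 p53 targets, 13 were higher and 4 lower, or 14 and 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.19). GDF15, a stress cytokine, rose from 6.37 ± 0.912 to 23.2 ± 0.888 FPKM, BBC3, which encodes the pro-apoptotic PUMA, rose by 1.05, and SFN fell by 0.51. Of 34 genes of nucleotide excision repair and other DNA repair, 8 were higher and none was lower, with the same counts adjusted over the list alone (camera adjusted p = 0.12). ERCC6, which acts in transcription-coupled excision repair, rose by 0.35, and BRCA2, which acts in homologous recombination, rose by 0.47. BRCA2 did not pass without UVB replicate 3, at a log2 fold change of 0.4581. Of 27 NRF2 targets, 3 were higher and 13 lower, or 3 and 14 adjusted over the list alone. ME1 and TKT fell by 0.64 and 0.55 (camera adjusted p = 0.00036 for the list, and adjusted p = 0.13 with an estimated correlation). The list's median was -0.17, and -0.11 without UVB replicate 2.

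Mitotic genes were lower after UVB. Of 35 genes of G2 and mitosis, 28 were lower and none was higher, or 30 lower adjusted over the list alone, with a median of -0.64 (camera adjusted p = 2.8e-18, and adjusted p = 0.046 with an estimated correlation). The kinesin gene KIF20A fell from 46.8 ± 1.26 to 12.5 ± 0.569 FPKM and CCNB1, which encodes cyclin B1, from 102 ± 5.40 to 42.8 ± 2.03 FPKM. MKI67 did not pass, at a log2 fold change of 0.07. S-phase genes were divided, with 6 of 30 higher and 7 lower, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.40). CDCA7 and MCM6 fell by 0.84 and 0.66, and CDT1 rose by 0.50. The S-phase list had a median of 0.02 and a mean of -0.09. Of 13 tested replication histones, 9 were lower and 1 was higher, also when adjusted over the list alone, with a median of -0.68 (camera adjusted p = 5.3e-05, and adjusted p = 0.046 with an estimated correlation). The histone median was -1.07 at a pseudocount of 0.1 and -0.45 without the expression filter. Histone copies are near-identical in sequence, so values such as the fall of 1.55 for HIST1H2AC are uncertain. Other members of the 20 listed lay under the expression filter. Among them, HIST1H4C had 4, 0 and 3 reads in controls and HIST1H1B had 14, 7 and 16. The list's result thus covers only the tested histones, and how fully the libraries captured histone mRNA was not tested.

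Keratinocyte genes changed in both directions. Of 18 basal keratinocyte genes, 3 were higher and 9 lower, over all genes and adjusted over the list alone. KRT15 fell from 50.1 ± 1.41 to 17.97 ± 0.475 FPKM and KRT5 from 287 ± 75.2 to 122 ± 36.6 FPKM, whereas KRT14, the partner of KRT5, rose by 0.43. The list's call (camera adjusted p = 0.0046) was lost with an estimated correlation (adjusted p = 0.21). Of 11 stress and simple keratins, 4 were higher and 3 lower, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.49). KRT6A, a keratin of wounded epidermis, rose from 13.4 ± 2.53 to 26.6 ± 0.226 FPKM. The mucosal keratin genes KRT13 and KRT4 fell from 2054 ± 116 to 624 ± 45.1 FPKM and from 98.4 ± 1.87 to 29.2 ± 1.18 FPKM. Of 15 tested differentiation genes, 3 were higher and 4 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.72). Among the tested genes, S100A8, S100A9, S100A7 and IVL were the 4 that fell, by 1.27, 1.16, 1.13 and 1.03. Other genes of the 47 listed lay under the expression filter and were not tested, and their reads moved in both directions. FLG had 571, 632 and 594 reads in controls and 262, 389 and 220 after UVB. KRT1 had 81, 144 and 141 against 12, 29 and 44, and SPRR1B had 0, 0 and 0 against 17, 21 and 9. This list had a median of 0.11 and a mean of -0.13. Of 28 matrix and protease genes, 8 were higher and 11 lower, or 8 and 12 adjusted over the list alone (camera adjusted p = 0.052). The list passed without control replicate 2 and without UVB replicate 3 (adjusted p = 0.0433 and 0.0443). TNC, which encodes tenascin C, and the protease gene MMP28 fell by 1.29 and 1.13, and PLAUR, the urokinase receptor gene, rose by 0.92.

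Among transcripts of the mitochondrial genome, 10 of 13 mRNAs were lower and none was higher, or 11 lower adjusted over the list alone, with a median of -0.32 (camera adjusted p = 8.2e-07, and adjusted p = 0.22 with an estimated correlation). MT-CYB (chromosome M, 14747 to 15887) fell from 4024 ± 195 to 1923 ± 34.7 FPKM, and MT-CO1 measured a log2 fold change of 0.02. The ribosomal RNAs MT-RNR1 and MT-RNR2 rose by 0.92 and 0.73. Mitochondrial ribosomal RNA took 1.77% ± 0.118 of reads in controls and 2.97% ± 0.0860 after UVB (SD, n = 3 each, 2-sided exact permutation p = 0.1, the smallest possible), while all mitochondrial reads took 8.12% ± 0.450 and 8.23% ± 0.208. Of 68 ribosomal protein genes, 27 were lower and none was higher, with the same counts adjusted over the list alone and a median of -0.16 (camera adjusted p = 2.3e-08, and adjusted p = 0.21 with an estimated correlation). With quantile normalization the ribosomal protein median was -0.08. As background, ribosomal protein genes have many processed pseudogenes, so reads of single genes are uncertain.

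**Figure D2:**
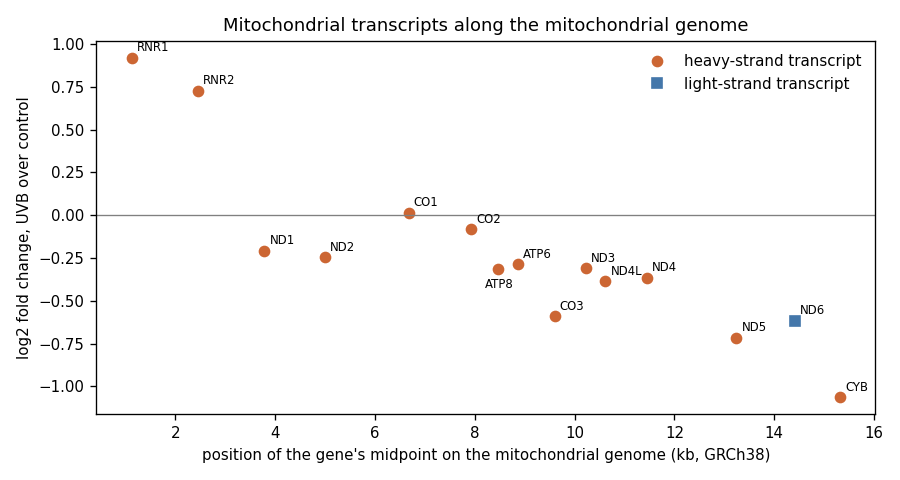
Log2 fold change (UVB over control, on log2(FPKM + 1)) of the mitochondrial mRNAs and ribosomal RNAs against the position of each gene's midpoint in kb (GRCh38). Circles are heavy-strand and the square is light-strand transcripts, with values from 0.92 for MT-RNR1 to -1.06 for MT-CYB.

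The cholesterol synthesis list stayed near 0, with 2 of 23 genes higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.81). DHCR7 and CYP51A1 rose by 0.43 and 0.40, the latter with 83.2% of its exon length shared with another gene. Both calls were lost without UVB replicate 2 (log2 fold changes of 0.4328 and 0.3636) or UVB replicate 3 (0.3929 and 0.4023), and that of CYP51A1 without control replicate 1 (0.3825). This list's median of 0.04 and its mean of -0.0066 differ in sign. Of 8 tested long non-coding RNAs, 2 were higher and 1 lower, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.71). NEAT1, which scaffolds paraspeckles, fell from 11.8 ± 3.69 to 5.51 ± 0.843 FPKM, and GAS5 rose by 0.69. The call of NEAT1 was lost without control replicate 1 or 2 or UVB replicate 1 or 3, at log2 fold changes of -0.8734, -0.7478, -0.8869 and -0.8788. Markers of other cell types were mostly under the filter, so these lists were not tested as sets. Of the melanocyte list 2 of 12 genes were tested and MITF was higher. Of the fibroblast list 1 of 14 was tested, COL1A1, and it was higher at 0.778 ± 0.137 and 1.75 ± 0.132 FPKM. Of the leukocyte list 2 of 16 were tested and CD68 was higher, with 85.8% of its exon length shared with another gene, and CD14 was lower only when adjusted over the list alone. Of the endothelial list 1 of 8 was tested, CDH5, which did not pass over all genes (limma adjusted p = 0.056), passed adjusted over the list alone, and passed over all genes without UVB replicate 3 (log2 fold change 0.586).

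**Figure D3:**
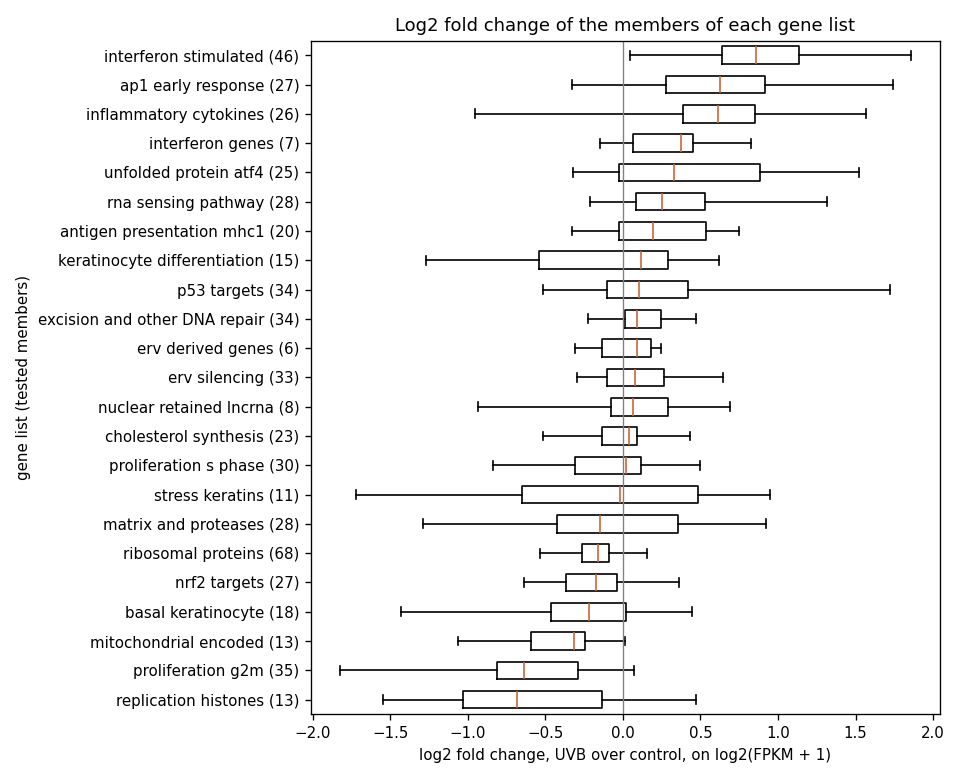
Log2 fold change (UVB over control, on log2(FPKM + 1)) of the tested members of each of 23 gene lists, ordered by median. Boxes span the quartiles, the coloured line is the median and whiskers reach the lowest and highest member. The interferon-stimulated list has a median of 0.86 and the G2 and mitosis list a median of -0.64.

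The protein-coding genes with the highest log2 fold changes on log2(FPKM + 1), an order that depends on the pseudocount, included genes outside the lists. GAST, which encodes the hormone gastrin (chromosome 17, 41712326 to 41715969), was at 0.443 ± 0.222 FPKM in controls and 9.68 ± 1.44 FPKM after UVB, a log2 fold change of 2.89 ± 0.151 (SE, limma adjusted p = 0.000139). CCL26, an eosinophil chemokine, rose from 1.52 ± 0.889 to 7.78 ± 0.388 FPKM and KLHDC7B from 0.124 ± 0.0201 to 3.51 ± 1.28 FPKM. C15orf38-AP3S2 and AL662899.2 had log2 fold changes of 3.11 and 2.98, but all of their exon length overlaps other genes, which leaves the origin of their reads uncertain. OLFM4, which encodes olfactomedin 4 (chromosome 13, 53028759 to 53052057), fell from 25.1 ± 0.737 to 3.08 ± 0.360 FPKM, a log2 fold change of -2.68 ± 0.0736 (SE, limma adjusted p = 4.6e-05). GMDS, an enzyme of GDP-fucose synthesis whose gene spans 621.9 kb of chromosome 6, fell from 12.02 ± 0.916 to 1.15 ± 0.208 FPKM. EDIL3, COMMD10, EXOC4, SCFD2, SMYD3, DPYD and SEMA5A also fell, by 2.17, 2.05, 1.91, 1.88, 1.88, 1.88 and 1.83. Of the 10 genes with the lowest log2 fold changes on this scale, 8 span over 300 kb.

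The second comparison asked which HERV copies differed. A deposited count sheet lists 74 repeat copies, of which 13 are named HERVH-int, the internal part of the HERVH family. In the authors' deposited table all 74 have a log2 fold change over 1 and a p-value under 0.01, and 39 have an adjusted p under 0.05, so the sheet is a selection of higher copies and its direction is not independent evidence. Summed over the sheet, these copies took 36.7 ± 1.71 RPM (reads scaled to the assigned reads of each library) in controls and 117 ± 8.66 after UVB (SD, n = 3 each). Normalised within the sheet, as the design had fixed, edgeR called 0 of 71 copies higher and 0 lower, with 6 higher and 4 lower at an unadjusted p under 0.05. Such scaling centres rows that all moved together. With library sizes from the whole table, edgeR called 70 of 70 copies higher. These copies had been selected as higher in the same libraries, so that count is not independent evidence either. When all copies of the deposited table were tested, limma called 10 of the sheet's copies. A DESeq2 Wald test within the sheet called 2 higher. Within the sheet, edgeR called 5 higher without control replicate 3, 1 without UVB replicate 1 and 5 without UVB replicate 3. The copy with the most reads, HERVH-int copy Repeat_276785.38438, had 298, 270 and 342 reads in the controls and 1025, 1224 and 970 reads after UVB. LTR16A copy Repeat_969180.145096 had 396, 310 and 367 reads against 1004, 945 and 994. LTR12C copy Repeat_3898051.630706 had 219, 146 and 171 reads against 583, 430 and 526. The next copies by reads, HERVH-int Repeat_276785.38441 and Repeat_276785.38440, belong to the same repeat number as the first and are not independent loci. That number accounts for 8 of the 74 copies. Other copies of the sheet carry consecutive running numbers and may not be separate loci either. Examples are LTR16C Repeat_987457.147405, LTR16C Repeat_987457.147406 and MLT1K Repeat_987461.147407.

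Because the sheet holds only higher copies, all repeat copies of the deposited table were tested as well, a comparison added after the data were seen. The authors' deposited table lists 57 repeat copies as higher and 100 as lower at an adjusted p under 0.05. Here limma called 12 of 7745 copies higher and 10 lower, with 322 and 513 at an unadjusted p under 0.05. The calls fall in 6 higher and 6 lower repeat numbers, which need not be separate regions. The called MLT1O copy Repeat_276786.38437 lies between Repeat_276785.38436 and Repeat_276785.38438 in the running numbers. Without coordinates the number of separate regions is not known. An edgeR test on the recovered reads called 4 of 9856 higher and 8 lower, with 310 and 548 at an unadjusted p under 0.05. Of the 22 copies called by limma, 8 also passed in edgeR. In simulated data limma found 13.2% of 4-fold increases among repeat copies, and 26% of its calls were unchanged copies, so single calls are weakly supported and an absence of calls says little. The balance depended on the settings, with 1 higher and 6 lower at a mean of at least 0.1 FPKM, 16 and 20 at a mean of at least 5 FPKM, and 14 and 5 with quantile normalization. Leaving out UVB replicate 1 lowered the counts to 3 and 4, and leaving out UVB replicate 2 or 3 or control replicate 3 lowered the higher count to 4, 7 and 7.

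HERVH copies changed in both directions. At repeat locus number Repeat_276785, 7 HERVH-int and LTR7Y copies were higher, among them the longest, HERVH-int Repeat_276785.38438, which rose from 1.23 ± 0.0326 to 3.92 ± 0.300 FPKM. In edgeR that copy passed (adjusted p = 0.00181), and the other called copies of this number did not (edgeR adjusted p from 0.0709 to 0.206). At locus number Repeat_1141665, HERVH-int Repeat_1141665.176943 fell from 49.7 ± 4.42 to 30.2 ± 1.86 FPKM and LTR7Y Repeat_1141665.176947 from 57.9 ± 3.17 to 32.0 ± 1.37 FPKM. At locus number Repeat_1909981, 4 HERVH-int copies were lower, with log2 fold changes from -0.46 to -0.64. Of these, only Repeat_1909981.286499 passed in edgeR (adjusted p = 0.0405, against 0.109, 0.115 and 0.16 for the others). The lower HERVH copies called by limma had far higher levels in controls than the higher ones. Summed over all its copies, HERVH-int took 1417 ± 109 RPM in controls and 1292 ± 44.9 after UVB, which did not pass (limma adjusted p = 0.47). LTR5_Hs copy Repeat_3419254.550737 fell from 2.49 ± 0.411 to 0.569 ± 0.126 FPKM. MLT1B copy Repeat_1631428.247714 had 165, 138 and 243 reads in the controls and 1 read in each UVB library. Coordinates of the repeat copies were not used here, so their neighbouring genes are not given.

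**Figure D4:**
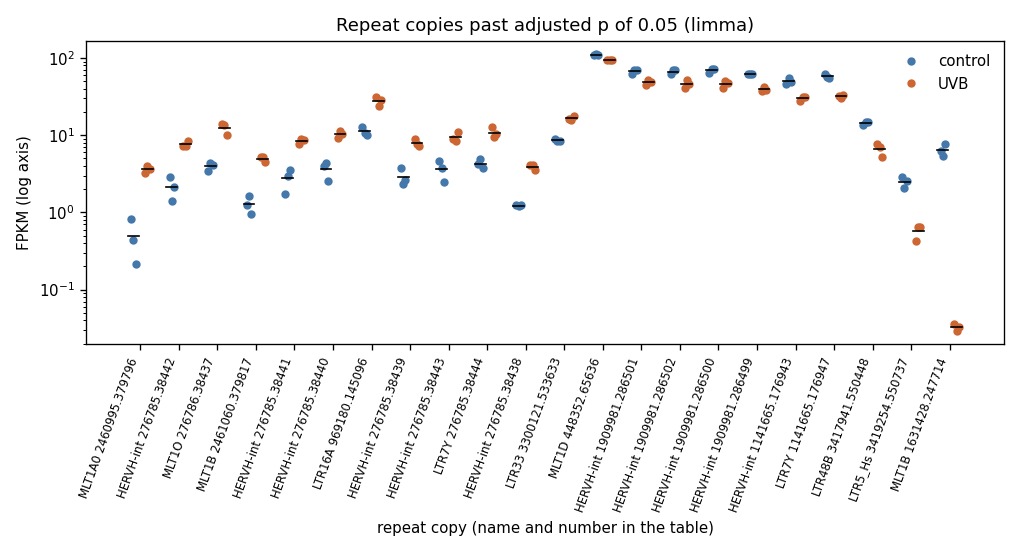
FPKM on a log axis of the 22 repeat copies past an adjusted p of 0.05 (limma), ordered by log2 fold change. Points are the 3 libraries of each group and black lines their means. HERVH-int Repeat_276785.38438 lies at 1.23 ± 0.0326 and 3.92 ± 0.300 FPKM, and HERVH-int Repeat_1141665.176943 at 49.7 ± 4.42 and 30.2 ± 1.86 FPKM.

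Reads were also summed by repeat name, another comparison added after the data were seen. Of 524 names with a mean of at least 50 reads, limma called 0 higher and 8 lower, with 3 and 84 at an unadjusted p under 0.05, and edgeR called 1 higher and 18 lower of 575. LTR48B fell from 16.3 ± 2.72 to 9.36 ± 0.699 RPM and HERV-Fc1-int from 3.79 ± 0.290 to 1.67 ± 0.176. Of the LTR48B reads, 1006, 1286 and 1211 in controls and 685, 886 and 684 after UVB, the called copy Repeat_3417941.550448 held 549, 574 and 721, and 334, 363 and 242. HERVK-int measured 28.1 ± 3.48 and 33.1 ± 1.67 RPM and did not pass (limma adjusted p = 0.31). The number of lower names depended on the libraries. It was 4 without control replicate 1, 3 without control replicate 2 and 37 without control replicate 3. It was 5, 4 and 4 without UVB replicates 1, 2 and 3, and 22 with TMM-scaled library sizes. A single name was higher without control replicate 3 and without UVB replicate 2. Of annotated genes derived from retroviruses, 6 of 22 listed were tested. ERV3-1 was lower over all genes, from 1.80 ± 0.132 to 1.27 ± 0.187 FPKM, but no member passed adjusted over the list alone (camera adjusted p = 0.71 for the list, which had a median of 0.09 and a downward test). The call of ERV3-1 was lost without each of the 6 libraries in turn. Its log2 fold changes were then -0.3335, -0.3186 and -0.2694 without control replicates 1, 2 and 3 and -0.2379, -0.3313 and -0.3523 without UVB replicates 1, 2 and 3. Of 33 genes that silence or restrict retroviral elements, 10 were higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.19). ZC3HAV1, the zinc-finger antiviral protein gene, and APOBEC3B rose by 0.65 and 0.54, the latter with 23.3% of its exon length shared with another gene.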

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

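Of 1894 alternative fits of the 113 named genes, 1832 stayed on the same side of the threshold, 59 lost the call and 3 gained it. No called gene changed sign, whereas MAVS, TBK1 and CCL5, which were not called, did in some fits. The 9 called genes of the RIG-I pathway and interferon response kept their calls. The interferon-stimulated, RNA-sensing, cytokine, early response, mitotic and histone lists passed in all 14 alternatives run for each. Alternatives for repeat copies and repeat names were chosen after seeing the data. At the depth and number of libraries here, 1.2% of simulated 2-fold increases of repeat copies were found (limma), and the part of depth in this was not tested. The causes of the shifts given here were not tested except where stated.

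For genes, requiring a mean of at least 5 FPKM left 990 lower genes, with fewer genes tested. Leaving out single libraries gave 1639 to 2074 higher and 1178 to 1332 lower genes, and UVB replicate 3 gave the lowest of both. The replicate block gave 1789 higher and 1240 lower genes. The numbers were not taken as pairs because no label ties them to a day or batch. Same-numbered libraries deviated together weakly (correlations across genes of 0.048, 0.022 and 0.030, genes not being independent). Each library nevertheless correlated best with its own number, so this check does not settle whether they are pairs. In the sheet the block called 2 copies higher and 1 lower, for repeat copies 10 and 7, for repeat names 1 and 14, and it ended the call of the MHC class I list (median 0.197).

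In the sheet, whose copies had been selected as higher in these same libraries, library sizes from the whole table called 70 higher. Scaling within the sheet centres copies selected in this way, and the DESeq2 Wald test called 2. Leaving out libraries gave 0 to 5 higher. With whole-table library sizes the log2 fold changes of the 5 copies with most reads turned from below 0 to 1.68, 1.31, 1.39, 1.595 and 1.4953. For repeat copies, higher and lower counts were 1 and 6 at a mean of at least 0.1 FPKM, 16 and 20 at 5 FPKM, 14 and 5 with quantile normalization, and 4 and 8 with the count test. Leaving out libraries gave 3 to 9 higher and 4 to 9 lower. For repeat names, TMM-scaled library sizes gave 1 and 22 and the count test 1 and 18. Leaving out libraries gave 0 to 1 higher and 3 to 37 lower.

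With an estimated correlation 6 lists lost their call at unchanged medians: MHC class I (0.197), basal keratinocyte (-0.217), mitochondrial (-0.317), NRF2 (-0.174), ribosomal protein (-0.158) and ATF4 (0.328). MHC class I also lost it at a pseudocount of 0.1 (median 0.200). Without a filter the silencing (0.0774) and DNA repair (0.0931) lists passed. Under fry, which does not compare a list with other genes, these lists passed in both the directional and the mixed test at unchanged medians: silencing (0.0781), DNA repair (0.0931), interferons (0.372), long non-coding (0.0641) and p53 (0.106), all upward, and matrix (-0.145), stress keratins (-0.022), differentiation (0.114) and S-phase (0.0218), all downward. The downward calls of differentiation and S-phase go with their means (-0.13 and -0.0892) and against their medians. Cholesterol (0.041) and retroviral genes (0.0922) passed in the mixed test alone. Leaving out libraries gave medians of 0.137 to 0.225 for MHC class I, 0.228 to 0.412 for interferons and -0.189 to -0.105 for matrix.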

Other observations

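Among genes named by the same rules and not described in the report, the cytokine gene IL1A rose from 8.35 ± 0.677 to 17.5 ± 0.157 FPKM, and HBEGF, a ligand of the EGF receptor, from 1.56 ± 0.0351 to 3.91 ± 0.286 FPKM (SD, n = 3 each). CD274, which encodes the immune checkpoint ligand PD-L1, rose from 0.496 ± 0.115 to 1.22 ± 0.0456 FPKM. The stress-induced SESN2 and the death receptor gene TNFRSF10A rose by 0.76 and 0.82 on the log2 scale. The integrin gene ITGA3, the desmosomal gene DSC3 and the plasminogen activator gene PLAT fell by 0.72, 0.55 and 0.77, and KRT19 fell from 909 ± 42.9 to 544 ± 22.1 FPKM. The kinetochore genes CENPE and CENPF fell by 1.28 and 0.98. In the count sheet, LTR5B copy Repeat_3730953.603853 had 8, 12 and 10 reads in the controls and 446, 527 and 11 after UVB, and MER84 copy Repeat_3321195.535995 had 5, 4 and 5 against 116, 140 and 3, so UVB replicate 3 was near the controls for both. These copies were chosen after their values were seen. Over all repeat copies of the table, 8001 in the controls and 8153 after UVB had at least 20 reads in a library of the group. In 178 and 180 of these, 2 libraries lay at least 10-fold above the remaining one, with at least 20 reads each. A single library lay at least 10-fold above the other 2 in 275 and 338.

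The tests of span and of mitochondrial position as such, of olfactory receptor and sense-intronic reads, and all splits of the samples were chosen only after the results were seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4167 called genes, 22 repeat copies, 8 repeat names and 0 sheet copies, and the highest of the other splits gave 3, 3, 2 and 2.

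Protein-coding genes with a long genomic span were more often lower. In the decile of longest span, from 143.5 kb, 31.6% were lower and 9.84% higher, while 6.99% to 14.2% were lower in the other deciles. The slope of centred log2 values on log10 span differed by -0.1111 (SE 0.0184) between UVB and control libraries, without overlap of the groups, though 3 against 3 libraries cannot give an exact p under 0.1 and genes are not independent. It remained with exon length (-0.1308), GC content (-0.0848) or mean level (-0.1148) in the regression, and with all 3 together (-0.108, SE 0.00423), which argues against each as the whole cause, although GC content itself correlated more with the fold changes across genes (rho 0.194) than span did (-0.143). No biological explanation was tested, and splicing, RNA stability and RNA quality stay open.

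Among the 12 heavy-strand mitochondrial mRNAs, the log2 fold change fell with position (rho -0.867 across genes, 2-sided permutation p = 0.00059). The relation remained given exon length (-0.869) and given GC content (-0.869), which argues against both as its cause. Overlapping pairs such as MT-ATP8 and MT-ATP6 share reads, and the genes come from 1 precursor RNA and are not independent. With the ribosomal RNAs rho was -0.916 over 14 genes (2-sided permutation p = 2e-05). No biological explanation was tested, and RNA stability stays open.

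More repeat names were lower than higher, with a median log2 difference of -0.18 (SE 0.0926) over all names tested. Reads on olfactory receptor genes, a measure of genomic DNA, differed by 0.0975 (SE 0.189), and reads on sense-intronic genes, a measure of intronic RNA, by 0.000189 (SE 0.0288). Without control replicate 2 the median was -0.0951 (SE 0.0555). With these errors, genomic DNA, intronic RNA, control replicate 2 and an effect of UVB cannot be told apart for this pattern.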
